A study of Escherichia coli str. K-12 substr. MG1655 with 2 samples.

How the data were processed

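RNA co-purified with the small RNA DsrA was sequenced from 2 Escherichia coli K-12 MG1655 libraries, 1 with DsrA carrying an MS2 aptamer (MS2-DsrA) and 1 with untagged DsrA as the control. In MS2-affinity purification with RNA sequencing (MAPS), a tagged small RNA is held on a column by the MS2 coat protein, and the RNAs bound to it are eluted and sequenced. Per the labels' protocols, the coat protein was fused to maltose-binding protein and bound to amylose resin (200 pmol on 100 µL of resin), the column was washed with 8 mL of buffer, RNA was eluted with 15 mM maltose, and libraries were made with a ScriptSeq v3 kit. Both growth phases, at an OD600 of 0.5 and of 1, are named together for each sample in the labels, and the table holds 1 read column per library, so the phases could not be examined apart.

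The deposited table holds whole-number read counts per gene and per intergenic region, per the file headers. Bowtie was used for alignment, per the submitters' processing notes; its version, the genome build, the counting tool, the use of strand and the treatment of reads with several matches are not given in the sources used here. Per the file headers, the authors also gave a normalized value and a ratio of MS2-DsrA to DsrA for each row. The normalized values equalled reads divided by 1 total per library, and the authors' ratio differed from the quotient of the normalized values by at most 0.0500, the rounding to its printed decimal. The totals implied by the authors' deposited normalized values were 4063700 reads for MS2-DsrA and 5488100 for DsrA, so the rows of the table held 86.6% and 86.5% of them. All 5 columns of values were assigned to a library or to the authors' comparison by name.

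The table has 7628 rows, of which 4347 are genes and 3281 are intergenic regions named after the genes on either side. Each row holds at least 1 read in both libraries, so no feature with 0 reads in a library is listed. Gene names, gene classes, lengths and neighbours came from the RefSeq gene table of assembly ASM584v2, in which 4322 of the 4347 genes were found and 25 were not; no coordinates are printed because the build of the deposited table is not given in the sources used here. Neighbouring rows can hold nearly equal reads, such as yncL with 267 reads and its flanking regions patD_yncL and yncL_ydcX with 258 each in the MS2-DsrA library. Whether a read was counted in more than 1 row is not given, so values of adjoining rows are not treated as independent, and reads of genes that overlap on opposite strands cannot be separated.

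Ratios of MS2-DsrA to DsrA were computed from the read counts, each divided by its library's total over all rows (3518006 reads for MS2-DsrA and 4748746 for DsrA). Printed ratios carry a 95% interval from the exact Clopper-Pearson method, conditional on the sum of the reads of both libraries; shares of a library carry exact Clopper-Pearson intervals too. These intervals cover counting error only, since there is 1 library per group. The reads have no molecular identifiers, so amplified copies of a fragment count as separate reads and the intervals may be too narrow even for counting error. For ranking and for calls, a pseudocount averaging 1 read, shared out by library size, was added to both libraries. A feature was called higher or lower when this ratio was at least 4-fold and its summed reads were at least 20. There is 1 library per group, so no test across replicates was run, no p-value is given, and differences between the libraries have no replicate check.

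Before the data were examined, 21 gene lists, the rule of size and the rule for named genes were fixed. The rule names DsrA and its listed targets, the 20 highest and 8 lowest genes by ratio, the 5 most abundant genes of each library, the 2 highest and 2 lowest members of each list with 5 or more genes above the read minimum, and genes within 100 bp of the 20 highest. The fixed rule asked for the same operon or strand, but the gene table gives no strand, so distance alone was used. Other genes named in the text were chosen after their values were seen. A list's median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean abundance in 10 bins, which describes these 2 libraries and is no test. The classes rRNA, tRNA, ncRNA and pseudogene from the gene table were treated as lists.

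Alternatives were scaling by edgeR's TMM (version 4.0.16) or by DESeq2's size factors (version 1.42.0) in R 4.3.3, both used only to scale, and scaling to the total without dsrA, rRNA and tRNA. Others were pseudocounts of 0.5 and 5 reads, no minimum or a minimum of 100 reads, rules of 2-fold and 8-fold, a rule on the near bound of the interval, matching in 20 bins, and shares without dsrA. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated counts for the 4347 genes of this comparison. Apart from the simulated folds, the counts were drawn with Poisson counting error around a mean shared by both libraries. They held no other variation between libraries and no shift of the median gene. The shares that follow are therefore not error rates of the calls in these data. All 40 genes raised 8-fold and all 40 genes lowered 8-fold were called, 2.5% of 40 genes raised 2-fold were called, and 0.0357% of 2799 unchanged genes were called. The interval held the simulated fold for 95% of the 40 genes raised 8-fold.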

Results

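DsrA is a small RNA of Escherichia coli that pairs with mRNAs with the help of the RNA chaperone Hfq. Among its textbook targets are rpoS, which encodes the stationary-phase sigma factor, and hns, which encodes the nucleoid protein H-NS. The design asks which RNAs co-purify with MS2-tagged DsrA, with untagged DsrA run over the same column as the control. The MG1655 strain lacked the chromosomal dsrA gene and carried rne131, an allele that shortens the endoribonuclease RNase E. DsrA or MS2-DsrA was induced with 0.1% arabinose for 10 min. There was 1 library per group, so the differences have no replicate check, and all intervals below are 95% intervals for counting error only.

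The MS2-DsrA library held 3518006 reads over the rows of the table and the DsrA library 4748746. The median feature had 14 reads with MS2-DsrA and 10 with DsrA. Ribosomal RNA took 82.7% of the MS2-DsrA reads (82.6% to 82.7%) and 78.2% of the DsrA reads (78.2% to 78.3%). The 23S genes held 57.2% and 57.3% of the reads, and the 16S genes 25.5% and 20.9%. Transfer RNA genes held 0.025% with MS2-DsrA and 0.0103% with DsrA. The 5 most abundant genes in both libraries were the 23S genes rrlB, rrlE, rrlC, rrlA and rrlH, with ratios of MS2-DsrA to DsrA from 0.985 to 0.990; reads of these near-identical copies cannot be assigned with certainty. The mRNAs hns, nlpD, rpoS and rbsD together took 2.76% of the MS2-DsrA reads (2.74% to 2.77%) and 0.0208% of the DsrA reads (0.0196% to 0.0222%). By contrast, rpsB, rplC, rplD and dps together took 0.210% of the MS2-DsrA reads and 4.95% of the DsrA reads, and both sets were chosen after their values were seen.

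The bait itself was barely sequenced. The dsrA gene had 8 reads with MS2-DsrA and 5 with DsrA, or 0.000227% (0.0000982% to 0.000448%) and 0.000105% (0.0000342% to 0.000246%) of the reads. Their ratio was 2.16 (0.623 to 8.39), so a difference in dsrA recovery between tagged and untagged DsrA was not detectable at this depth. The adjoining region yodD_dsrA held the same 8 and 5 reads, and yodD had a ratio of 1.63 (1.04 to 2.55). On the other side, the region dsrA_yedP had 9 reads and 1 read, a ratio of 12.1 (1.68 to 532), and yedP had 25 and 2 reads, 16.9 (4.21 to 147), which met the rule of size.

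Established and predicted DsrA targets were strongly represented with the tagged bait. The hns mRNA had 29725 reads with MS2-DsrA and 162 with DsrA, a ratio of 248 (212 to 291) that ranked 1st of the 2999 genes with at least 20 reads. The authors' deposited table gives 247.8 for the same gene. The rbsD mRNA, encoding D-ribose pyranase, had a ratio of 74.3 (60.6 to 92.1) from 5176 and 94 reads, and rpoS had a ratio of 52.1 (47.2 to 57.7) from 15294 and 396 reads. The argR mRNA, encoding the arginine repressor, had 83 and 16 reads and a ratio of 7.0 (4.07 to 12.8).

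The remaining 3 listed targets did not meet the rule of size. The ratio was 3.01 (1.87 to 4.98) for lrp, the leucine-responsive regulator, 1.80 (0.696 to 4.84) for ilvI, a subunit of acetolactate synthase, and 1.22 (0.805 to 1.85) for mreB, the actin-like cell shape protein. Thus 4 of the 7 listed targets were at least 4-fold higher and none was at least 4-fold lower. The list's median was 6.60-fold, at percentile 99.95 of matched random lists. The place of rbsD among DsrA targets is partly known from work on these libraries, so it is not independent evidence. Since the median gene had a ratio of 1.64, hns lay 151-fold, rbsD 45.4-fold, rpoS 31.8-fold and argR 4.28-fold above it. With TMM scaling the pseudocounted ratio of argR was 3.73, short of the rule. The ratio of mreB, 1.22 to library totals, lay below 1 at 0.745 when set against the median gene.

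**Figure D1:**
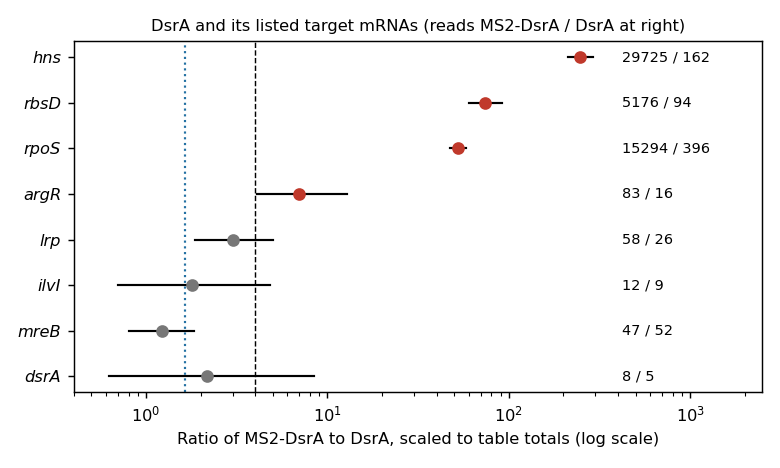
Ratio of MS2-DsrA to DsrA reads, scaled to table totals, for the 7 listed targets and dsrA on a log axis, with 95% counting intervals as bars, reads at the right, the 4-fold rule as a dashed line and the median gene as a dotted line. The points for hns, rbsD, rpoS and argR, in red, lie beyond 4-fold, and the interval of dsrA reaches from 0.623 to 8.39.

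Reads at the 3 strongest target loci spread over neighbouring features. Upstream of rpoS, nlpD had 46777 and 338 reads and a ratio of 187 (168 to 209), and the region between them, rpoS_nlpD, had a ratio of 132 (112 to 156). The gene nlpD encodes an activator of cell wall amidases and contains the main rpoS promoter, so its 3' part is shared with the rpoS leader. The ratio was lower on both sides, at 4.95 (3.34 to 7.51) for pcm and 7.65 (2.21 to 40.7) for ygbN. At hns, the region hns_tdk had a ratio of 228 (177 to 298), while tdk had 7.56 (2.88 to 25.1) and galU 2.11 (1.44 to 3.13).

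The ribose operon showed a ratio that differed along its genes. The ratio was 123 (47.7 to 454) in the region kup_rbsD ahead of rbsD, but 1.26 (0.563 to 2.80) for kup itself, 74.3 for rbsD and 12 (8.93 to 16.4) for rbsA, the transporter ATPase. It was 1.26 (0.977 to 1.64) for the permease gene rbsC and 5.22 (4.73 to 5.78) for rbsB, the ribose-binding protein. The region rbsB_rbsK had 11.1 (9.56 to 12.9), the ribokinase gene rbsK had 1.82 (1.34 to 2.48) and the repressor gene rbsR 2.89 (1.11 to 8.39). Of the 6 listed ribose genes, 3 were at least 4-fold higher, or 2 when set against the median gene, and the list lay at percentile 98.35. The list holds rbsD, whose place among DsrA targets is partly known from work on these libraries. The percentile is therefore not independent evidence either. The counting intervals of rbsA, rbsC and rbsB do not overlap, but they hold no spread between libraries.

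**Figure D2:**
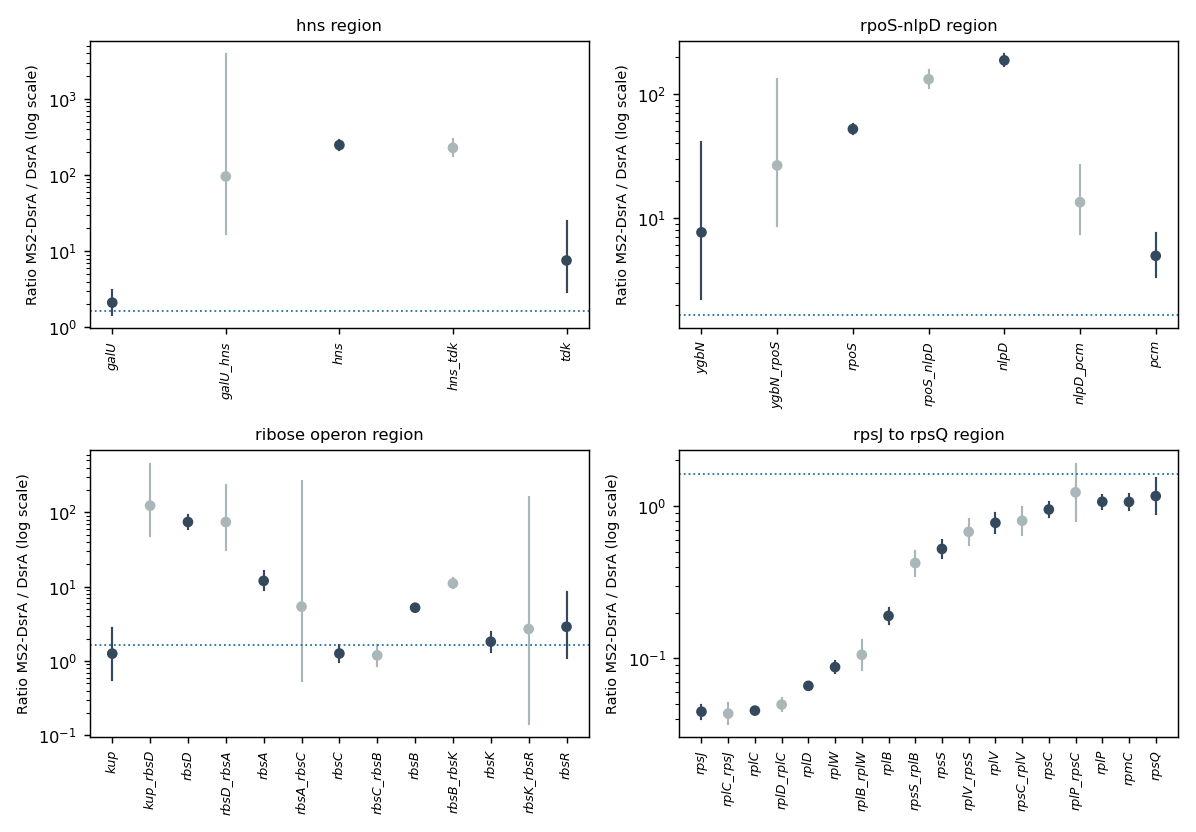
Ratio of MS2-DsrA to DsrA reads on log axes for genes (dark) and intergenic regions (light) at 4 regions. Bars are 95% counting intervals, and a dotted line marks the median gene's ratio of 1.64. Features are in chromosome order, except that the region from rpsJ to rpsQ is reversed so that it starts with rpsJ. The hns, rpoS and rbsD regions peak at 248, 187 and 123, and the region from rpsJ to rpsQ runs from 0.0447 at rpsJ to 1.17 at rpsQ.

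Across the genome, 441 of the 2999 genes were at least 4-fold higher with MS2-DsrA and 169 were at least 4-fold lower. Beside hns, nlpD, rbsD and rpoS, the 20 highest genes included yciY, of unknown function, at 66.6 (45.6 to 101), and yciI at 46.0 (25.4 to 93.0). The region clsA_yciY between the cardiolipin synthase gene and yciY had 58.3 (40.2 to 88.2), and kch, a potassium channel gene beside yciY, had 5.30 (3.42 to 8.49). They also included yjbJ at 33.9 (22.5 to 53.3) and bolA, a regulator of cell morphology, at 23.2 (18.0 to 30.2). Others were the small open reading frame yncL at 32.8 (18.0 to 66.4), gnsB at 29.5 (17.3 to 54.6), ygdQ at 32.9 (13.7 to 103), the protease gene ptrA at 25.2 (14.5 to 48.1) and tatE, a component of twin-arginine transport, at 23.3 (14.3 to 40.5). Genes within 100 bp of these had lower ratios than the gene they adjoin. The adjoined genes were chosen as the highest, so this follows largely from the choice and is no evidence of a local peak. The ratio was 6.11 (4.28 to 8.93) for the recombination gene recB beside ptrA and 5.10 (2.40 to 12.1) for the zinc regulator gene zur beside yjbJ. The mismatch repair gene mutH beside ygdQ had 17.5 (2.64 to 746), from 13 reads and 1 read, under the read minimum. Beside yncL, the dehydrogenase gene patD had 2.19 (1.35 to 3.6), short of the rule.

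Several of the 20 highest genes rested on few control reads. The antisense RNA gene symR had 77 reads with MS2-DsrA and 1 with DsrA, a ratio of 104 (18.1 to 4158), and reads of symR cannot be separated from those of symE, which it overlaps and which had 22 and 2 reads, 14.8 (3.65 to 130). The activator gene marA of the multiple antibiotic resistance operon had 54 reads and 1 read, a ratio of 72.9 (12.5 to 2932), while marR had 18.9 (6.04 to 95.3) and marB, with 6 and 2 reads, 4.05 (0.724 to 41.0). The pseudogene pawZ' had 47.2 (7.94 to 1919), with 6.30 (3.34 to 12.9) for torI and 2.89 (1.11 to 8.39) for dsdC beside it, and ybeD had 35.1 (11.6 to 174). The tRNA genes leuZ, cysT and glyW, which lie side by side, had ratios of 33.1 (12.5 to 124), 44.5 (11.9 to 375) and 27.4 (8.96 to 137).

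The split of higher and lower genes depended on the scaling. Against library totals, 72.3% of the called genes were higher. Set against the median gene, 172 genes were at least 4-fold higher and 299 at least 4-fold lower, so 36.5% of calls were higher, and TMM and DESeq2 scaling both gave 145 higher and 324 lower genes (30.9%). Without dsrA, rRNA and tRNA in the total, 655 were higher and 123 lower (84.2%). Among the 1401 intergenic regions with at least 20 reads, 263 were higher and 95 lower, or 124 and 156 against the median gene. The whole counting interval lay beyond 4-fold for 162 higher and 102 lower genes.

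**Figure D3:**
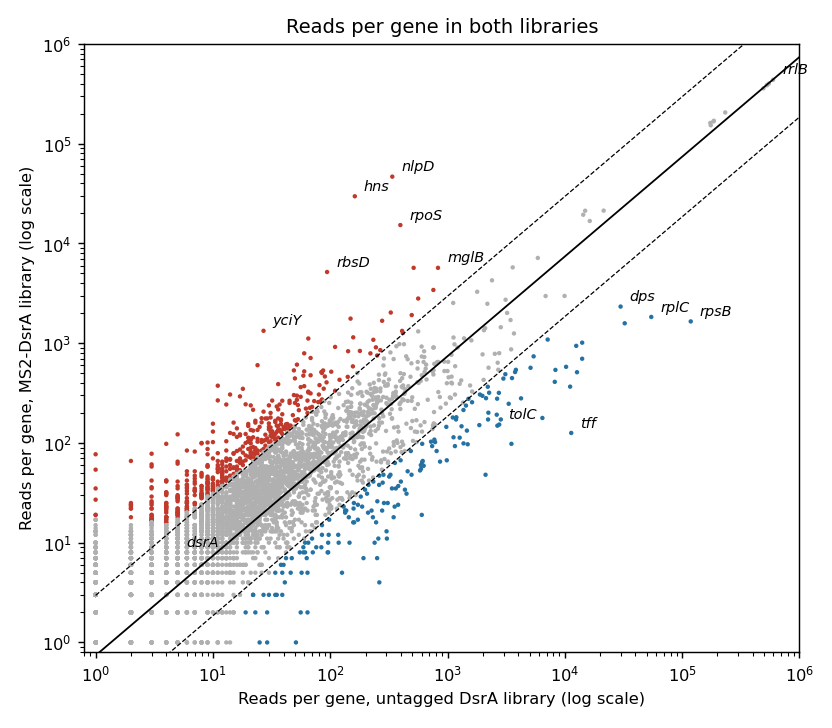
Reads per gene in the DsrA library (x axis) and the MS2-DsrA library (y axis), both on log scales, with genes at least 4-fold higher in red, at least 4-fold lower in blue and others in grey; the solid line marks equal shares of both libraries and the dashed lines 4-fold. The genes nlpD, hns, rpoS and rbsD stand above the rest at 5176 or more reads, and rpsB with 1654 and 118295 reads lies far below the lines.

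Transcripts recovered mainly with untagged DsrA included abundant ribosomal protein mRNAs. The rpsB mRNA, encoding ribosomal protein S2, had 1654 reads with MS2-DsrA and 118295 with DsrA, 53.0-fold lower with MS2-DsrA (50.5 to 55.7). The small RNA gene tff, just upstream, was 66.6-fold lower (55.9 to 80.0), and tsf, the elongation factor gene downstream, was 14.9-fold lower (13.8 to 16.1). The genes beyond them, map and pyrH, had ratios of 0.450 (0.238 to 0.806) and 0.487 (0.349 to 0.670). In the operon that starts with rpsJ, examined after its values were seen, the ratio went up along the genes. It was 0.0447 (0.0401 to 0.0496) for rpsJ, 0.0454 (0.0433 to 0.0476) for rplC, 0.0660 (0.0628 to 0.0695) for rplD, 0.0877 (0.0802 to 0.0957) for rplW and 0.190 (0.169 to 0.214) for rplB. It reached 0.524 (0.460 to 0.597) for rpsS, 0.778 (0.666 to 0.907) for rplV and 0.952 (0.851 to 1.06) for rpsC.

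The other genes among the 8 lowest included dld, yhhM and the neighbours ynfH and dmsD and yphB and yphC. The D-lactate dehydrogenase gene dld was 26.8-fold lower with MS2-DsrA (23.1 to 31.3), from 178 and 6434 reads. The neighbours ynfH and dmsD were 32.5-fold (24.4 to 44.3) and 26.5-fold lower (21.7 to 32.7). The neighbours yphB and yphC were 23.5-fold (14.9 to 39.3) and 26.6-fold lower (12.7 to 66.8), and yhhM was 48.5-fold lower (18.7 to 179), from 4 and 262 reads. The stationary-phase DNA-binding protein gene dps was 9.49-fold lower (9.10 to 9.91), from 2330 and 29855 reads. The ATP synthase genes atpG and atpA were 10.3-fold (9.64 to 11.0) and 9.84-fold lower (9.21 to 10.5), tolC 13.4-fold (11.3 to 15.8) and the RNA helicase gene deaD 13.2-fold (11.2 to 15.7).

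Small RNAs that act with Hfq were higher with MS2-DsrA as a list. Of the 30 listed, 24 were found, as no feature with 0 reads in a library is listed. Of these 24, 23 had a ratio above 1 and 19 lay above the median gene, but 15 had fewer than 20 reads. A ratio above 1 was common, in 3044 of 4035 protein-coding genes and 46 of 54 ncRNA genes. The only one below 1, ryfA, was among those 15, at 0.123 (0.00285 to 0.844) from 1 and 11 reads. Of the 9 with at least 20 reads, 4 were at least 4-fold higher, or 3 against the median gene, and none was lower. The carbon metabolism regulator spf had 349 and 18 reads and a ratio of 26.2 (16.3 to 44.7), arcZ had 10.8 (6.05 to 21.0), omrB 15.5 (3.84 to 136) and micF 7.65 (2.21 to 40.7), the last pair from 2 and 3 control reads. The genes omrB and micF reached the read minimum mostly through their MS2-DsrA reads, 23 and 17. The lowest of the 9 were gcvB at 1.80 (1.40 to 2.32) and gadY at 1.75 (0.942 to 3.32). The list lay at percentile 98.37, and at 94.6, within the central range, when genes with few reads were kept. The region polA_spf next to spf held 365 and 19 reads. The genes arcZ and micF were singled out after their values were seen.

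Genes that H-NS represses also had higher ratios as a list. Of the 20 found, 16 had a ratio above 1 and 4 below, 15 lay above the median gene, and 6 had fewer than 20 reads. Of the 14 with at least 20 reads, 7 were at least 4-fold higher and 1 was lower, or 2 and 1 against the median gene. The list lay at percentile 99.94. Among the 7, bglG, csgD and yjjQ reached the read minimum mostly through their MS2-DsrA reads, 18, 20 and 22, against 2, 5 and 6 with DsrA. The lysine decarboxylase gene cadA had a ratio of 6.86 (5.53 to 8.56), cadB 5.19 (3.49 to 7.91) and bglG, an antiterminator gene, 12.1 (2.91 to 108) from 18 and 2 reads. The fimbrial subunit gene fimA went the other way and was 4.21-fold lower (3.01 to 6.02), and adiA was at 0.956 (0.482 to 1.86). Annotated pseudogenes had a median of 3.24-fold, with 21 of 72 at least 4-fold higher, or 4 against the median gene, and lay at percentile 100.

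Motility genes went both ways, and few were covered. Of the 24 found, 13 had a ratio of MS2-DsrA to DsrA above 1 and 11 below, with a median log2 ratio of 0.29, or -0.42 relative to the median gene. Among those with few reads, the flagellar sigma factor gene fliA had 4.72 (0.900 to 46.6) and the master regulator gene flhD 2.25 (0.741 to 7.53), both named after their values were seen. Only 5 genes had 20 or more reads, and the flagellin gene fliC among them had a ratio of 2.43 (1.37 to 4.43). The other 4 met the rule of size as lower and reached the minimum mostly through their DsrA reads. The chemoreceptor gene tsr, from 12 and 97 reads, was 5.99-fold lower (3.28 to 12) and the motor gene motB, from 9 and 76 reads, 6.26-fold lower (3.13 to 14.2). The chemotaxis genes cheA and cheW, which lie next to motB, had 2 reads each with MS2-DsrA, against 64 and 29 with DsrA, and ratios of 0.0422 (0.00500 to 0.159) and 0.0931 (0.0108 to 0.368). The median log2 ratio of these 5 genes, -2.54, lay at percentile 0 of matched lists, and that of all 24 at 2.48 with no minimum of reads.

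**Figure D4:**
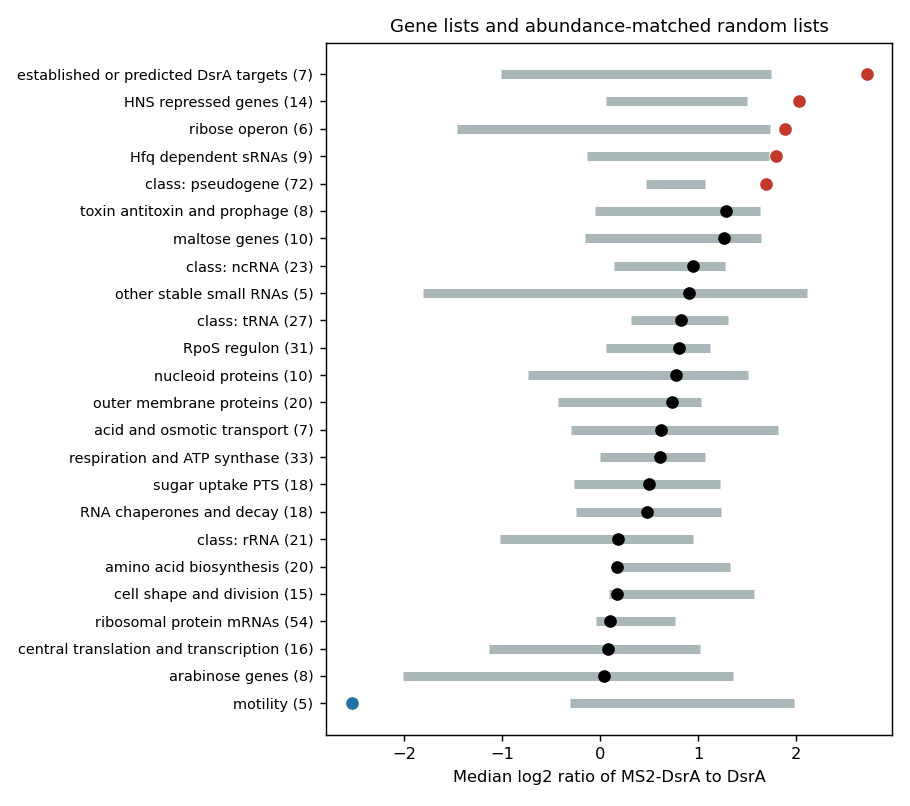
Median log2 ratio of MS2-DsrA to DsrA for the 24 ranked gene lists (points, number of genes with at least 20 reads in brackets) over the central 95% of the medians of 10000 abundance-matched random lists (grey bars). In red, 5 lists lie above their bars, in blue the motility list, with 5 of its 24 genes, lies below at -2.54, and 18 lists, in black, lie within.

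The other 18 lists lay within their matched range, with members that went both ways in many of them. In the RpoS regulon (percentile 80.84), 6 of 31 genes were at least 4-fold higher and 1 lower, or 3 and 2 against the median gene, with bolA at 23.2 and the catalase gene katE at 10.5 (6.55 to 17.6) set against dps and osmC at 0.105 and 0.290. Of 54 ribosomal protein mRNAs (percentile 11.45), 4 were higher and 6 lower, or 0 and 7 against the median gene. Their highest ratios were 7.42 (3.07 to 21.7) for rpsU and 6.09 (5.63 to 6.60) for rplL. Of 10 nucleoid protein genes with at least 20 reads (percentile 72.99), only hns was higher, with hha next among them at 3.54 (2.46 to 5.17). The genes dps and hupA were lower, the latter by 4.49-fold (3.91 to 5.17). A further member, stpA, had 7.20 (2.06 to 38.6) from 16 and 3 reads, under the read minimum. Of 33 respiration and ATP synthase genes (percentile 62.63), 0 were higher and 3 lower, and nuoH and nuoI of complex I had ratios of 3.64 and 3.48.

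Sugar uptake genes (percentile 52.79) included mglB and mglA, the galactose-binding protein and transporter ATPase, at 9.28 (8.62 to 9.99) and 7.90 (6.60 to 9.51), while fruA and nagE were 7.31-fold and 9.43-fold lower. Outer membrane protein genes (percentile 86.59) ran from ompW at 8.18 (7.20 to 9.32) and fepA at 8.10 (3.38 to 23.5) to ompA at 0.404 and tolC. Of 8 arabinose genes (percentile 50.19), none was called, from araD at 1.24 and araF at 1.15 to araC at 0.721 and araG at 0.418. Of 10 maltose genes (percentile 89.11), malZ was higher at 5.91 (2.69 to 14.7), but 0 were higher against the median gene. Of the others, malS had 4.05 and malQ and malT had 0.554 and 0.716. Amino acid biosynthesis genes (percentile 2.84) ran from ilvD at 4.64 (2.62 to 8.68) and serA at 2.88 to thrA at 0.417 and argG, 6.51-fold lower. None of 15 cell shape and division genes (percentile 3.96) was called, from murB at 3.93 and ftsL at 3.54 to ftsZ at 0.711 and ftsA at 0.350.

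RNA chaperone and decay genes (percentile 47.24) had proQ higher at 4.31 (3.75 to 4.97), but 0 were higher against the median gene. The gene cspI was at 2.61, and deaD and rne were lowest, with 0.543 for rne. Translation and transcription factors (percentile 35.01) had nusG at 8.87 (6.25 to 12.9), infA at 6.80 (5.01 to 9.41) and infB at 6.74 (6.15 to 7.39), with tsf, described above, and nusA, at 0.321, as the lowest. Acid and osmotic transport genes (percentile 41.38) had mscL at 8.95 (6.25 to 13.2), betT at 5.29, kefB at 0.787 and betA 7.23-fold lower. Toxin-antitoxin and prophage genes (percentile 87.58) had relE at 5.87 (3.58 to 10.1), relB at 5.30, mazE at 1.37 and hipA at 1.35. Other stable small RNAs (percentile 78.17) had csrB at 4.38 (3.91 to 4.90), csrC at 3.24, rnpB at 1.83 and ssrA at 1.54. The classes rRNA, tRNA and ncRNA lay at percentiles 52.02, 53.87 and 80.84.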

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

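The settings that compare with the median gene, and the totals implied by the authors' normalized values, were chosen after the data were seen; the others were set before. The separate or summed growth phases could not be tried, because the table has 1 read column per library. No paired analysis was possible because each group has 1 library. For genes, the main counts of 441 higher and 169 lower became 145 and 324 with TMM and with DESeq2 scaling, 172 and 299 over the median gene, 1209 and 372 at 2-fold, 117 and 62 at 8-fold, and 162 and 102 on the near bound of the interval, and 198 genes were higher at a minimum of 100 reads. For intergenic regions, 263 higher and 95 lower became 114 and 171 with TMM, 115 and 171 with DESeq2, 124 and 156 over the median gene, 638 and 190 at 2-fold, 91 and 40 at 8-fold, 102 and 46 on the near bound, and 71 and 58 at a minimum of 100 reads. Higher regions numbered 168 with a pseudocount of 5 and 432 with no minimum. These moves follow from each setting's construction. TMM and DESeq2 scaling lowered the median log2 ratio of genes by 0.83 (a shift of -0.83), and leaving dsrA, rRNA and tRNA out of the totals moved it by 0.32. Over the settings run per gene, the pseudocounted ratio ranged from 136 to 309 for hns, 40.8 to 92.3 for rbsD, 28.8 to 65.4 for rpoS and 3.73 to 8.25 for argR, whose call ended under TMM and DESeq2 scaling, so that 3 of the 7 targets stayed at least 4-fold higher, and from 0.0105 to 0.0238 for rpsB. With no minimum of reads, 2 lists lay below their matched lists, with amino acid biosynthesis at percentile 1.40 and motility at 2.48. At a minimum of 100 reads, 2 lists lay above (ribose operon and pseudogenes) and 0 below, because the targets, the Hfq-dependent small RNAs, the genes repressed by H-NS and the motility genes then had under 5 members each and were not ranked. The balance of calls turned from mostly higher to mostly lower with TMM, DESeq2 and the median gene, for genes and for intergenic regions. Over the settings run per gene, no gene chosen by the naming rule that met the rule of size changed direction, while genes that did not meet it, such as mreB (0.681 to 1.52) and rbsC (0.702 to 1.59), did. Depth limits dsrA and the genes with 1 to 3 control reads.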

Other observations

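Tests on bait capture, rRNA copy orientation, ribosomal protein content and the rpsB fragment were written after the values they measure had been seen; the tests on neighbouring genes were written before their pair counts were computed, but after neighbouring genes with similar ratios had been noticed. Reads ahead of 16S in some forward operons had also been seen before that test.

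Genes of lipopolysaccharide core synthesis, chosen after their values were seen, lay above the median gene over much of the waa cluster. The ratio of MS2-DsrA to DsrA was 14.7 (11.0 to 20.1) for waaJ, 14.1 (11.0 to 18.4) for waaU, 11.7 (8.98 to 15.6) for waaS, 10.8 (8.24 to 14.4) for waaZ and 7.56 (5.49 to 10.6) for waaY. It was 6.96 (5.54 to 8.82) for waaL, 5.34 (3.88 to 7.50) for waaP and 4.23 (3.00 to 6.09) for waaB, while waaQ and waaG at the other end had 1.5 (1.05 to 2.16) and 1.15 (0.774 to 1.69). A further sugar transport gene, ytfQ, had 5701 and 514 reads and a ratio of 15.0 (13.7 to 16.4), and the region ytfQ_ytfR had 26.2 (20.6 to 33.9). On the lower side, the trehalose-6-phosphate hydrolase gene treC was 18.4-fold lower (16.8 to 20.1), the fatty acid activation gene fadD 14.8-fold lower (13.4 to 16.4) and galT of galactose use 13.1-fold lower (12 to 14.3).

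One hypothesis is that MS2-DsrA carried along stretches of transcript, so that genes at least 4-fold above the median gene lie side by side. Among 2383 adjacent pairs of measured genes, 29 had both members that high, against at most 17 in 1000 shuffles of the genes, which is consistent with it. Genes that share an operon also share a transcript level, and reads may be counted in more than 1 row, which the shuffles do not separate from it.

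The dsrA gene had only 8 reads with MS2-DsrA, where it was the bait, and 5 with DsrA, which carried no tag. The adjoining region yodD_dsrA held the same 8 and 5 reads, so whether these reads come from the induced RNA is not known. A failure to capture the tagged bait is argued against by hns and rpoS, whose lower bounds lay at least 28.8-fold above the median gene. The gene rbsD passed the same rule, but its place among DsrA targets is partly known from work on these libraries. The rule was written after the values were seen. Poor representation of short RNAs may account for the few dsrA reads with MS2-DsrA. In that library, 16S rRNA genes had 88.2 times the reads per kb of 5S rRNA genes, and with DsrA 70.7 times. Small RNAs were not all poorly read, however. With MS2-DsrA and DsrA, spf had 349 and 18 reads and gcvB 152 and 114, while ffs had 6 and 2 and rprA 2 and 1. No biological explanation was tested.

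The rRNA genes differed between copies in both libraries. Each copy in the 5 operons in which 16S comes before 23S on the reference held at least 7.18 times the reads of each copy in the 2 operons of the other orientation, for 16S and 23S alike, and placement of reads from repeated genes by orientation is a candidate explanation. A difference in operon expression remains open. The region ahead of 16S in those 2 operons held at most 0.135 of the forward median, but the leader regions may themselves be repeated. The 5S genes of the 2 operons went opposite ways. With MS2-DsrA and DsrA, rrfD had 255 and 398 reads and rrfG 1 read each, against forward 5S medians of 79 and 87. The ratio also differed between copies, at 1.83 and 1.93 for rrlD and rrlG and 0.985 to 0.990 for the 5 forward copies.

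Genes lower with MS2-DsrA than with untagged DsrA also lay side by side, with 114 adjacent pairs of genes both at least 4-fold below the median gene against at most 38 in 1000 shuffles, which take no account of shared operons or of reads counted in more than 1 row. At rpsB, all 5 features from tff to tsf had upper bounds at least 4-fold lower, so the lower ratio was not confined to 1 row. Whether a single fragment was amplified there is not decided by this. The rule was written after these values were seen, and adjoining rows may share reads. A difference between the cultures in ribosomal protein mRNA content stays open. The 48 other ribosomal protein genes had a median log2 ratio of -0.49 relative to the median gene (SD 0.84), against -3.10 to -6.44 for the 6 genes of the rpsB and rpsJ segments, but their upper quartile, -0.23, did not lie above the median gene as the test asked before excluding it.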
